A study of Mus musculus with 6 samples.

How the data were processed

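Poly-A RNA of neutrophils from the dura mater of mice was sequenced, with 3 libraries labelled male and 3 labelled female, all taken after exposure to a social threat. Per the labels' protocols, RNA was extracted with Trizol, poly-A RNA was purified with poly-T beads and fragmented, and complementary DNA was made with random primers and sequenced on an Illumina NovaSeq. The protocol names no step that marks the strand. Per the submitters' processing notes, cutadapt 1.15 and HISAT2 2.0.5 were used with the mouse genome GRCm39, with no role or order stated. The counting tool and its handling of strand and of shared reads are not given in the sources used here. The authors deposited raw counts per gene, whole numbers for 21955 Ensembl gene identifiers in each of the 6 libraries, with no normalization.

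Symbols, chromosomes and gene types came from a GENCODE annotation of an older mouse build, which named 21847 of the identifiers. Since the builds differ, no coordinates are printed. Of the identifiers, 21719 were protein-coding, so most non-coding RNAs, Xist among them, are not analysed here. Antisense and overlapping genes cannot be told apart without strand, and near-identical paralogs are uncertain.

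Samples were grouped by the sex given in their labels. Nothing in the labels says that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 4.19 to 17.4), so none was a copy of another. This does not show separate animals, as separate preparations of 1 pool would differ too. Each library was taken as 1 replicate. Library sizes were 18272577, 17270072 and 17098026 counts for those labelled male and 18555944, 19003104 and 20778410 for those labelled female. Principal component 1 held 38.0% of the variance.

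Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10, quasi-likelihood fit and test, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. This left 11903 genes, with a common biological coefficient of variation of 0.0696. Log2 fold changes are libraries labelled female minus those labelled male, and the SE of each was derived from the change and its F statistic. Gene lists, 40 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with an estimated correlation and fry as companions. Of 941 list entries 923 matched a row. Single measures per library were compared by exact two-sided permutation tests. The interval of the Y-linked ratio assumes normal log2 sums with a pooled SD, and covers the spread between libraries.

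The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes Xist and 4 Y-linked genes; the 8 largest fold changes per direction among other called genes with non-overlapping groups, a mean of at least 1 log2 CPM and an established symbol; up to 4 members of each called list and of the neutrophil state, interferon, TNF and glucocorticoid lists; and the most abundant member of each list for another cell type. It gave 98 genes, of which the text gives a part. Genes outside it illustrate lists or families and were chosen after their values were seen.

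Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 3 libraries, stricter thresholds, leaving out each library, the replicate number as a block, the other list tests, lists without X- and Y-linked genes and, added after seeing the data, the counts without mitochondrially encoded genes.

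The pipeline was tested on simulated counts with the means, sizes and dispersions of these libraries. It recovered 71.7% of 99 genes changed 1.5-fold and 90% of 100 genes changed 2-fold, and called 0.13% of 11548 unchanged genes, among 11820 fitted. The test had first required more than 90% of the 2-fold genes; after that value came out at 90% itself the requirement was lowered to 75%, with the pipeline unchanged. Simulated genes were independent, so the simulation does not test the preset correlation.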

Results

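RNA was sequenced from neutrophils of the dura mater, the outer layer of the meninges, taken from wild-type mice after exposure to a social threat. There were 6 libraries in 2 groups, 3 labelled male and 3 labelled female, and no library from unexposed mice. The design implies 1 comparison, which asks how the state of these cells after exposure differs between the sexes. Total counts over genes ranged from 17098026 to 20778410 per library, with 19450000 ± 1176000 in the libraries labelled female and 17550000 ± 634300 in those labelled male (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Levels below are CPM after TMM normalization, given as mean ± SD of 3 libraries.

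Genes of the Y chromosome were read as a check on the labels, and they were expressed at similar levels in both groups. Ddx3y (ENSMUSG00000069045), which encodes an RNA helicase, had 136 ± 2.31 CPM in the libraries labelled male and 136 ± 6.64 CPM in those labelled female. Eif2s3y (ENSMUSG00000069049), a translation initiation factor subunit, had 139 ± 4.01 and 147 ± 7.81 CPM. The histone demethylase genes Kdm5d (ENSMUSG00000056673) and Uty (ENSMUSG00000068457) had 25.4 ± 1.84 and 12.47 ± 2.485 CPM in the libraries labelled male, against 26.9 ± 1.88 and 13.02 ± 2.214 CPM. Their sum was 313 ± 5.88 CPM in the libraries labelled male and 322 ± 8.94 CPM in those labelled female. The ratio of the sums was 1.03 (95% interval 0.975 to 1.09; exact two-sided permutation p = 0.3, where the smallest possible is 0.1). Each library held between 5148 and 6597 counts over these 4 genes, and none of the 4 passed the test between groups (adjusted p from 0.475 to 0.995 by edgeR's quasi-likelihood test).

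**Figure D1:**
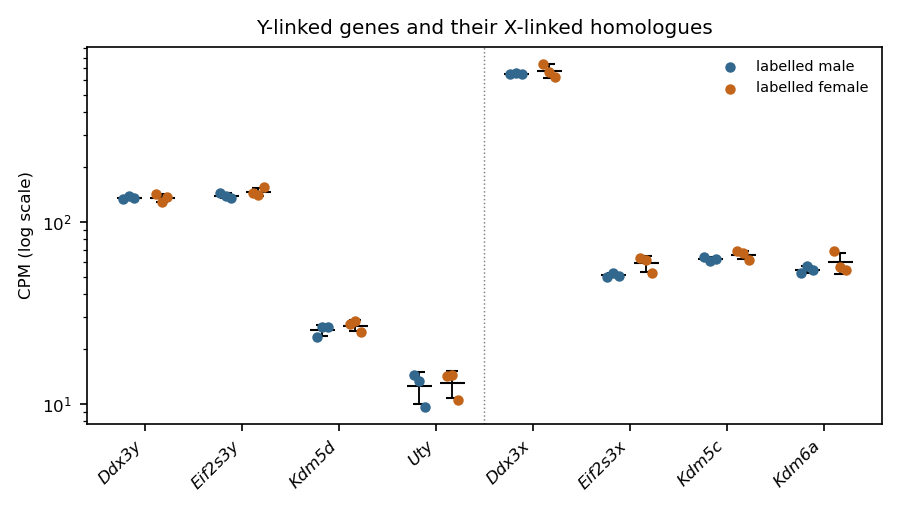
CPM (log scale) of 4 Y-linked genes, left of the dotted line, and of their X-linked homologues, right of it. Points are single libraries, blue for those labelled male and orange for those labelled female, and bars show the mean ± SD of 3 libraries. Ddx3y stood at 136 CPM in both groups.

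The Y-linked genes therefore go against the label female in all 3 libraries that carry it. Groups are named by their labels throughout, and a direction drawn between them is a difference between libraries so labelled, not a measured difference between female and male mice. Among 6 X-linked genes that escape inactivation, Utp14a was higher in the libraries labelled female by 0.23 on the log2 scale (SE 0.069, adjusted p = 0.0293). This call, the only one in the list, was lost without male replicate 1, 2 or 3 (adjusted p = 0.103, 0.095 and 0.0878) or female replicate 2 (0.178), and 3 genes were higher without female replicate 3. Eif2s3x (log2 0.22, adjusted p = 0.0581), Kdm6a (0.14, adjusted p = 0.305), Kdm5c (0.08), Pbdc1 (0.07) and Ddx3x (0.05) did not pass. The list as a whole did not pass either (adjusted p = 0.0799 by camera with a preset correlation). Xist, the RNA of the inactive X chromosome, is not analysed here.

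The libraries labelled female had lower levels of interferon-stimulated genes and of several early response genes, and higher levels of genes of mature neutrophils. Of 53 type I interferon response genes, 42 were lower in the libraries labelled female and 1 was higher, with a median fold of 1.57. Of 20 mature neutrophil genes, 17 were higher, with a median fold of 1.41. Markers of B cells and dendritic cells and mitochondrially encoded transcripts were lower in the same libraries, and globin transcripts were higher.

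Of 11903 genes tested, 868 were higher and 788 lower in the libraries labelled female at an adjusted p under 0.05. Of these, 1597 were autosomal, 832 higher and 765 lower. Of 363 X-linked genes 49 passed, 35 higher and 14 lower. The median fold of the called genes was 1.25, and 47 higher and 74 lower genes changed at least 2-fold. In 97.0% of the called genes, and in 30.9% of all tested genes, the values of the groups did not overlap, where chance gives 10% for a single gene. Genes that move together can exceed that share in 1 division of the libraries. Called genes were selected for a difference, so neither share is a test of the groups. The counts moved when 1 library was left out. A fit to fewer libraries has less power, so a call lost there need not rest on the library left out. Without the libraries labelled male replicate 1, 2 or 3 there were 503, 486 or 439 higher and 522, 496 or 467 lower genes. Without the library labelled female replicate 2 there were 521 lower genes, and without female replicate 3 there were 1439 higher and 1269 lower. The chi-square per degree of freedom of female replicate 3 was 14.1 and 17.4 against the other libraries labelled female, and 5.33 between those.

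Among genes with an established symbol, a mean of at least 1 log2 CPM and groups that did not overlap, the largest increase in the libraries labelled female was that of Prok2 (ENSMUSG00000030069, chromosome 6), a secreted peptide that attracts myeloid cells. It rose from 1.79 ± 0.0197 to 6.93 ± 1.45 CPM (log2 1.95, SE 0.22, adjusted p = 3.45e-06). Sycp2, a component of the synaptonemal complex, rose from 3.603 ± 0.7996 to 11.98 ± 0.735 CPM, 3.31-fold. Acod1, the enzyme that makes itaconate, rose 2.94-fold from 17.2 ± 2.81 to 50.59 ± 10.04 CPM. The others among the 8 largest increases by this rule were Rhov (3.12-fold), Stfa2 (2.99-fold), Hbb-bs (2.90-fold), Ankrd33b (2.86-fold) and Gpr27 (2.81-fold). The largest decrease was that of Rtn2 (ENSMUSG00000030401, chromosome 7), a reticulon of the endoplasmic reticulum, from 5.16 ± 0.959 to 0.911 ± 0.278 CPM (log2 -2.49, SE 0.28, adjusted p = 3.03e-06). Fam71a, of which 41.5 ± 5.06 CPM were found in the libraries labelled male, was 3.14-fold lower at 13.2 ± 0.334 CPM. The other 6 of the 8 largest decreases by the same rule were Phf11d, Ifit3, Oasl1, Ifit3b, Ifi213 and Ifi44, each at least 3.09-fold lower. All but Ifi213 stand in the list of type I interferon response genes. Ifit3 and Ifit3b are near-identical copies, as are several globin, stefin and Ifi200 genes, and how their shared reads were counted is not given in the sources used here.

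Type I interferon response genes made up the list with the largest count of changed genes. Phf11d was 4.49-fold lower in the libraries labelled female, at 3.90 ± 0.445 against 17.5 ± 1.65 CPM (adjusted p = 2.70e-09). Ifit3, which restricts viral RNA, was 3.62-fold lower at 9.30 ± 0.999 against 33.7 ± 3.85 CPM. Oasl1 was 3.42-fold lower and Ifit3b 3.23-fold lower. The exception was Ifitm1 (2 genes rose without female replicate 3), singled out after its values were seen, which rose 2.15-fold from 24.0 ± 3.08 to 51.6 ± 3.85 CPM. With p-values adjusted over the list alone, 44 genes were lower and 2 higher. The list fell against all other genes (adjusted p = 9.25e-41 by camera with a preset correlation; adjusted p = 0.0856 with an estimated correlation). Beside it, 11 of 21 genes of interferon gamma and antigen presentation fell and none rose by edgeR, among them the MHC class II genes H2-Eb1 (to 99.95 ± 10.45 CPM), H2-Ab1 (1.58-fold) and the invariant chain Cd74 (1.56-fold). Adjusted over the list alone, 12 were lower, and the list fell (adjusted p = 6.35e-11 by camera; adjusted p = 0.142 with an estimated correlation). B cell and dendritic cell markers, described below, fell in the same libraries as both lists.

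**Figure D2:**
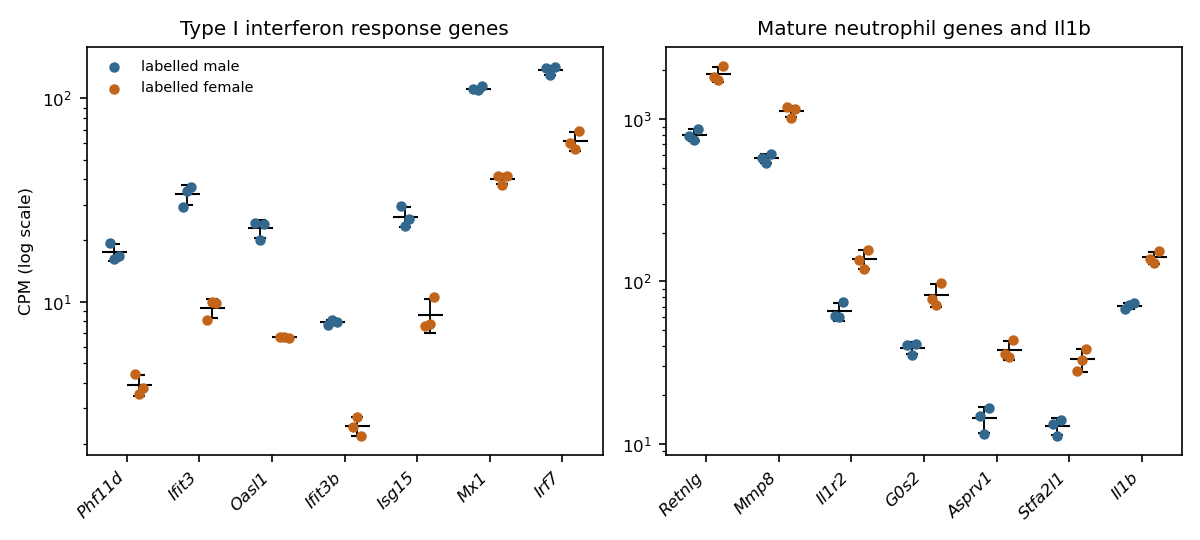
CPM (log scale) of type I interferon response genes, left, and of mature neutrophil genes with the cytokine gene Il1b, right. Points are single libraries and bars the mean ± SD of 3. Ifit3 lay at 33.7 CPM in the libraries labelled male and at 9.30 CPM in those labelled female, and Retnlg at 800 and 1903 CPM.

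Mature neutrophil genes rose in the libraries labelled female. Retnlg, a resistin-like protein of neutrophils, rose from 800.4 ± 64.7 to 1903 ± 210 CPM (2.38-fold, adjusted p = 7.23e-10). Asprv1 rose 2.65-fold, Stfa2l1 2.59-fold and G0s2, an inhibitor of lipolysis, 2.12-fold. Adjusted over the list alone 19 of the 20 rose, and the list rose (adjusted p = 1.19e-23 by camera; adjusted p = 0.217 with an estimated correlation). Of 17 genes of secondary and tertiary granules 7 rose, and likewise 7 adjusted over the list alone. They included Arg2 (2.62-fold) and the secreted proteases Mmp8 (1.95-fold) and Mmp9 (1.70-fold), of which the last pair also stand in the mature list. The abundant granule genes Ngp (log2 0.12), Ltf (0.13) and Camp (0.09) did not pass the test. The granule list rose (adjusted p = 2.56e-06 by camera; adjusted p = 0.497 with an estimated correlation).

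Of 20 receptors of chemotaxis and adhesion, 9 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell (2 fell at the all-gene threshold without female replicate 2). The chemokine receptor Ccr1 rose 1.90-fold to 209 ± 12.4 CPM, and the receptors of formylated peptides Fpr1 and Fpr2 rose 1.773-fold and 1.498-fold. P2ry2, a nucleotide receptor, rose 1.96-fold, a call lost without male replicate 3 (adjusted p = 0.111) or female replicate 2 (adjusted p = 0.0956). The list rose (adjusted p = 0.000108 by camera; adjusted p = 0.217 with an estimated correlation).

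Other lists tied to the neutrophil state had members on both sides and did not pass the list test. Of 11 primary granule genes, Hp was higher (log2 0.23, adjusted p = 0.0464) and Mpo, the myeloperoxidase gene, lower (log2 -0.21, adjusted p = 0.0315). Without male replicate 1, 2 or 3 neither call held (adjusted p = 0.0772, 0.195 and 0.163 for Hp, and 0.137, 0.106 and 0.107 for Mpo). Without female replicate 3 Hp had a log2 change of 0.12 and adjusted p = 0.0803, and without female replicate 1 or 2 Mpo had adjusted p = 0.144 or 0.0606. Hp also missed the threshold with upper-quartile factors (adjusted p = 0.0614) and with a filter of 10 CPM (adjusted p = 0.0625). Without female replicate 3, 3 primary granule genes fell. Of 14 genes of neutrophil ageing and retention, 4 rose and 4 fell, among them Cxcl2 (1.37-fold higher) and Itgax (1.38-fold lower). There, 2 rose without male replicate 2, and the number that fell was 2 without male replicate 1 or female replicate 2 and 1 without male replicate 3. Of 11 genes of the NADPH oxidase and extracellular traps, 3 rose, including Padi4 (1.30-fold), and 1 fell. Without male replicate 1, 2 or 3 only 1 rose, and the number that fell was 2 without female replicate 3 and 0 without any other library. Of 34 cell cycle genes, 2 fell and none rose by edgeR. Without female replicate 3, 6 fell and 2 rose, without male replicate 3 none fell by edgeR, and without any other library 1 fell.

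Early response genes were mostly lower in the libraries labelled female, and genes of inflammation went both ways. Of 25 immediate early and dissociation genes 16 fell and 2 rose, and adjusted over the list alone 18 fell and 2 rose. Egr3 fell 2.01-fold and Nr4a2 1.596-fold, and Fosb, the most abundant of those named here, fell from 1848 ± 26.5 to 1196 ± 20.9 CPM. The list fell (adjusted p = 1.55e-12 by camera; adjusted p = 0.142 with an estimated correlation). Of 32 TNF and NF-kB response genes 11 fell and 4 rose (7 fell without male replicate 1), and adjusted over the list alone 12 fell and 5 rose. Gadd45b, a stress-induced regulator, fell 2.67-fold, the costimulatory Cd83 2.28-fold and Tnf 2.01-fold. Il1b, the gene of interleukin 1 beta, rose 1.99-fold to 141 ± 11.9 CPM. This list fell (adjusted p = 0.000396 by camera; adjusted p = 0.204 with an estimated correlation).

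Of 19 glucocorticoid response genes 9 fell and 2 rose, and adjusted over the list alone 12 fell and 2 rose (at the all-gene threshold 1 rose without male replicate 1, 2 or 3). Cdkn1a fell 1.34-fold, and Il1r2, the decoy receptor of interleukin 1, rose 2.11-fold. Map3k6 fell 1.40-fold, a call lost without male replicate 3 (adjusted p = 0.0715). The list fell (adjusted p = 0.00111 by camera; adjusted p = 0.234 with an estimated correlation).

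Of 21 glycolysis genes 5 rose and none fell by edgeR, and adjusted over the list alone 5 rose and 1 fell. The lactate exporter Slc16a3 rose 1.93-fold, and the glucose transporters Slc2a1 and Slc2a3 rose 1.39-fold and 1.28-fold. The list rose (adjusted p = 0.0058 by camera; adjusted p = 0.557 with an estimated correlation). Of 20 hypoxia response genes 5 rose, including Slc2a1 again and Hif1a (1.23-fold), and 1 fell (3 rose without male replicate 2 or 3). Adjusted over the list alone 6 rose and 1 fell. This list was near the threshold (adjusted p = 0.0483 by camera; adjusted p = 0.224 with an estimated correlation), with adjusted p = 0.0811 without male replicate 2 and 0.057 without female replicate 1.

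Mitochondrially encoded transcripts took 7.43 ± 1.04% of counts in the libraries labelled female and 11.99 ± 1.23% in those labelled male (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Of 12 such genes 8 fell, and 9 adjusted over the list alone. mt-Co1, a subunit of cytochrome c oxidase, fell from 63510 ± 7721 to 38550 ± 6794 CPM. The list fell (adjusted p = 9.81e-12 by camera; adjusted p = 0.224 with an estimated correlation). With these genes left out before library sizes were computed, an alternative chosen after seeing the data, 834 other genes were higher and 838 lower. Of 78 cytosolic ribosomal protein genes 7 fell, and 5 adjusted over the list alone, with a median log2 change of -0.09 (adjusted p = 2.12e-06 by camera; adjusted p = 0.695 with an estimated correlation). That count was 0 without male replicate 1 or female replicate 1, 3 without male replicate 2, 2 without male replicate 3 or female replicate 2, and 44 without female replicate 3. The median was -0.04 without female replicate 1 and -0.15 without female replicate 3. The mitochondrially encoded and ribosomal protein lists had been set as measures of RNA quality. A difference in RNA quality between the groups was not tested.

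Markers of other cell types also differed between the groups. Of 19 B cell genes 9 fell in the libraries labelled female, and 13 adjusted over the list alone. The surface markers Cd22 (1.74-fold) and Ms4a1 (1.73-fold) were among them. The B cell list fell (adjusted p = 1.48e-07 by camera; adjusted p = 0.4 with an estimated correlation). Of 15 dendritic cell genes 10 fell, and 13 adjusted over the list alone. The migration receptor Ccr7 fell 2.06-fold from 24.84 ± 3.749 to 12.03 ± 1.134 CPM, Clec9a 1.69-fold and Ccr9 1.596-fold. The dendritic cell list fell (adjusted p = 2.81e-12 by camera; adjusted p = 0.0944 with an estimated correlation). Bst2 stands in both the dendritic cell and the type I interferon lists.

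Of 13 erythroid genes 5 rose (3 without female replicate 2), and 7 adjusted over the list alone. The globin gene Hbb-bs rose from 8.89 ± 1.72 to 25.9 ± 9.08 CPM and Hba-a1 from 8.37 ± 0.877 to 16.4 ± 4.18 CPM. The list rose (adjusted p = 0.000527 by camera; adjusted p = 0.142 with an estimated correlation). Of 15 fibroblast and matrix genes, Igfbp5 fell 2.10-fold, Apod fell 3.12-fold at under 2 CPM, and Acta2 rose 1.71-fold. Adjusted over the list alone 4 fell and 1 rose. This list fell (adjusted p = 0.0434 by camera; adjusted p = 0.224 with an estimated correlation), with adjusted p = 0.054 without female replicate 1. Apod had adjusted p = 0.0745 without male replicate 1 and 0.05025 without female replicate 1. Counts of fallen genes in it were 3 without male replicate 1, 5 without female replicate 3 and 1 without female replicate 1.

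**Figure D3:**
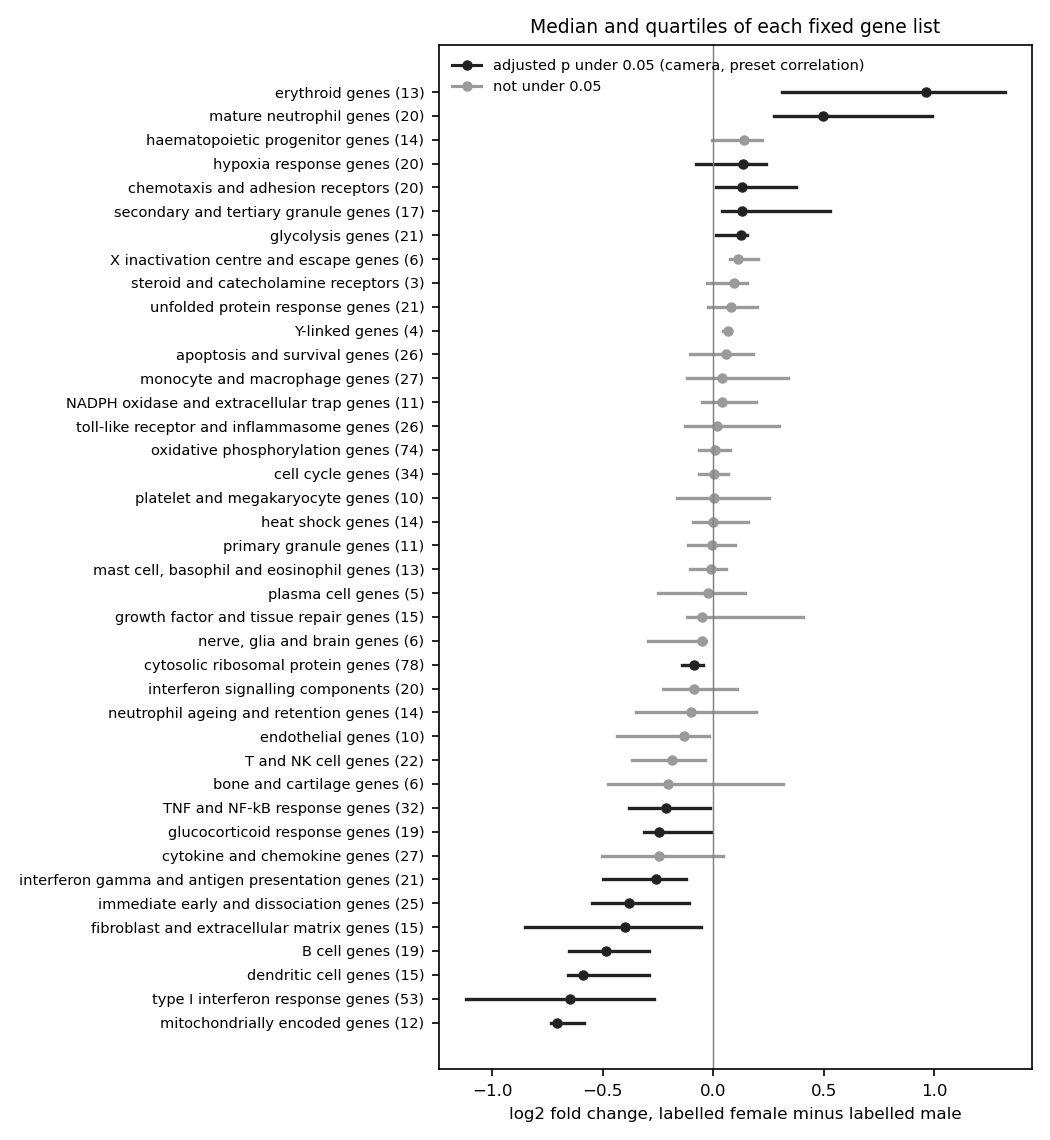
Median (point) and quartiles (line) of the log2 fold change, libraries labelled female minus those labelled male, for 40 gene lists, with the number of tested genes in brackets. Black lists had an adjusted p under 0.05 by camera with a preset correlation, and none did with an estimated correlation. The medians of the mitochondrially encoded and type I interferon lists were -0.71 and -0.65.

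In all, 16 of 40 lists passed the list test with the preset correlation, 6 higher and 10 lower. None of the 16 calls held with an estimated correlation, and 12 lists passed by fry, which asks whether the genes of a list move one way and does not compare it with other genes. By fry the interferon signalling list was gained (adjusted p = 0.00579), and 5 of the 16 calls were lost. These were secondary and tertiary granule (adjusted p = 0.114), glycolysis (0.117), mitochondrially encoded (0.069), ribosomal protein (0.373) and B cell genes (0.0929). Other ways of dividing the same 6 libraries into 3 and 3 gave up to 15 lists past the threshold with the preset correlation, but 0 genes by edgeR; each of these mixes the labels and keeps part of the difference between them.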

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

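The setting without mitochondrially encoded genes was chosen after seeing the data, and the others before. Under both other scalings, DESeq2, limma-voom, both filters and the setting without mitochondrially encoded genes, total counts of higher, lower and autosomal genes stayed within 1.5 times. Mast cell, basophil and eosinophil genes that fell were 3 without mitochondrially encoded genes, against 1 with them. DESeq2 called 1644 genes, of which 1584 were shared with edgeR, all in the same direction, and limma-voom 1640, of which 1601 were shared. Of 87 called named genes, 68 were tested in every other fit at 0.05, left-out libraries included, and 55 of these stayed past the threshold in the same direction in all. The other 19, mostly below the filter of 10 CPM, were not tested in at least 1 fit, and 14 of them stayed past it where tested. No result past the threshold with all 6 libraries turned its direction.

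At a threshold of 0.01, 410 genes were higher and 410 lower in the libraries labelled female, 790 of the called genes autosomal. At 0.05 with a fold of at least 2 these were 47, 74 and 118. Fewer genes pass either limit by construction. Leaving out 1 library gave 439 to 1439 higher, 467 to 1269 lower and 872 to 2599 autosomal genes, lowest without male replicate 3 and highest without female replicate 3. The cause of these moves was not tested. Lists past the threshold numbered 14 to 20 without 1 library, 12 by fry and 0 with an estimated correlation, and the cause was not tested. The erythroid, hypoxia and fibroblast lists had estimated correlations of -0.000236, -0.0207 and 0.000821, below the preset 0.01. Their unadjusted p by camera still rose, from 0.000158, 0.0193 and 0.0163 to 0.0161, 0.0632 and 0.0633. A larger correlation therefore does not account for these losses. Estimated correlations of the other called lists ranged from 0.0268 to 0.787. The hypoxia list missed the threshold without a filter (adjusted p = 0.0888), with at least 10 CPM (0.074) and without X- and Y-linked genes (0.0884). The fibroblast list missed it in the last of these settings (0.0705) and with at least 10 CPM (0.509), where the erythroid list also missed it (0.0613).

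Replicate numbers occur in both groups, and no label says what they share. Same-numbered libraries deviated with correlations of -0.0435, 0.0584 and 0.0534, and libraries of different numbers with -0.131 to 0.0857. These values, from deviations around means of 3 libraries, do not show what the numbers share. They cannot exclude a common day or batch. With the number as a block, 1007 genes were higher, 914 lower and 1850 autosomal, with 17 lists.

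Of 34 values that turned direction, for lists by the direction of the list test, 33 were past the threshold in neither fit, with log2 values from -0.105 to 0.056. The other was the oxidative phosphorylation list, which fell without female replicate 3 (median log2 -0.0654, adjusted p = 0.0285; range without 1 library -0.0654 to 0.0498). Without a filter the log2 values were 0.0083 for Ddx3y, 0.0031 for Nkg7 and primary granule genes and 0.013 for cell cycle genes. With at least 10 CPM the list medians were 0.038 for ageing and retention, -0.024 for cytokines, -0.0080 for oxidative phosphorylation and -0.035 for monocytes. The mast cell list had -0.013 with the block and -0.013 by fry, and apoptosis 0.056 by fry. Over left-out libraries, Uty ranged from -0.092 to 0.20, Ddx3y from -0.033 to 0.038, Fn1 from -0.12 to 0.018, Xbp1 and the plasma cell list from -0.064 to 0.0080, and Nkg7 and primary granule genes from -0.048 to 0.048. List medians ranged from -0.17 to -0.021 for ageing and retention, -0.043 to 0.084 for NADPH oxidase, -0.0062 to 0.012 for cell cycle, -0.041 to 0.16 for monocytes and -0.087 to 0.032 for mast cells. The cause of these turns was not tested. At this depth genes near 1 CPM rest on about 20 counts per library.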

Other observations

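Families of related genes were tested after their values were seen, 7 in all, each by Fisher's exact test against all tested genes with adjustment over both directions. Of 12 HIN-200 genes, which encode sensors of nucleic acids, 11 were lower in the libraries labelled female (median 1.68-fold, adjusted p = 1.58e-11). Among them Ifi213 fell from 81.0 ± 2.86 to 25.5 ± 0.679 CPM. Guanylate-binding proteins were lower in 4 of 8 genes (adjusted p = 0.00753) and Schlafen genes in 3 of 7 (adjusted p = 0.0193). Stefin A genes, inhibitors of cysteine proteases, were higher in 3 of 5 (adjusted p = 0.0161), both formyl peptide receptors were higher (adjusted p = 0.0171), and so were 4 of 11 genes of the interleukin 1 family (adjusted p = 0.0171). Of 8 Clec4 lectins 1 was higher (adjusted p = 0.909). Several members also stand in the lists described above, so the families are not independent of them. The families were chosen with the calls in view, and the test treats related genes as independent. Their p-values are therefore descriptive and lend no support beyond the single genes.

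Among monocyte and macrophage genes 5 of 27 rose and 4 fell, and the list did not pass (adjusted p = 0.7 by camera; 3 rose without male replicate 2 and 8 without female replicate 3). Ccr2, a receptor of classical monocytes, rose from 613.5 ± 28.4 to 879 ± 58.7 CPM in the libraries labelled female, while Fcgr1 fell from 48.7 ± 2.37 to 30.0 ± 3.84 CPM. Pattern receptor and inflammasome genes went both ways, with 6 of 26 higher and 4 lower. Of 14 heat shock genes, 3 rose, and the inducible Hspa1a and Hspa1b fell by 1.03 and 1.41 on the log2 scale. Numbers higher and lower in the other lists that did not pass were 3 and 6 of 20 for interferon signalling, 5 and 6 of 27 for cytokines, 4 and 3 of 21 for the unfolded protein response, 1 and 2 of 26 for apoptosis, 3 and 1 of 15 for growth factors, 3 and 1 of 14 for haematopoietic progenitors and 1 and 1 of 13 for mast cells, basophils and eosinophils. They were 1 and 0 of 74 for oxidative phosphorylation, 1 and 0 of 10 for platelets, 1 and 0 of 3 for steroid and catecholamine receptors, 0 and 1 of 22 for T and NK cells, 0 and 1 of 6 for nerve and glia, and 0 and 3 of 6 for bone and cartilage. No plasma cell gene of 5 and no endothelial gene of 10 passed by edgeR.

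Many of these small counts moved when 1 library was left out. Without male replicate 1, 2 interferon signalling genes fell, no unfolded protein response gene rose by edgeR, and 1 endothelial gene fell. Unfolded protein response genes that rose were 0 without male replicate 3 and 1 without male replicate 2 or female replicate 2. Oxidative phosphorylation genes that fell were 11 without female replicate 3, where 2 rose, and none rose by edgeR without male replicate 2 or 3. Bone and cartilage genes that fell were 1 without male replicate 2 or 3 or female replicate 2. Progenitor genes that rose were 1 without male replicate 3 and 5 without female replicate 3, and none fell by edgeR without male replicate 1 or 3. Growth factor genes that fell were 0 without male replicate 1 or female replicate 2 and 2 without female replicate 3. Apoptosis genes that rose were 0 without male replicate 1, 2 or 3 and 2 without female replicate 3. Those that fell were 4 without female replicate 3 and 1 without male replicate 2 or 3 or female replicate 1 or 2. The call among steroid and catecholamine receptors was lost without any library but female replicate 3, where 1 of them also fell. Mast cell, basophil and eosinophil genes that fell were 0 without male replicate 2 or female replicate 1 and 2 without female replicate 2 or 3, and 2 rose without the last. T and NK cell genes that fell were 0 without male replicate 2 and 2 without female replicate 2, where 1 endothelial gene also fell. Without female replicate 1, 1 plasma cell gene rose, and without female replicate 3, 1 nerve and glia gene rose.

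The tests in the next 3 paragraphs, and that of mitochondrial transcripts, were chosen after the result was seen; those of the splits and of clock genes were set before. Y-linked transcripts stood at the same level in libraries labelled female and male. Reads of X-linked homologues are argued against as the source of Eif2s3y, which was 2.50 times as abundant as Eif2s3x in the libraries labelled female. For Ddx3y, Kdm5d and Uty the ratios to their homologues were 0.202, 0.407 and 0.218 there. They were near those in the libraries labelled male (0.209, 0.409 and 0.229), with a lower 95% bound between groups of 0.863. This argues against misassigned reads only if the libraries labelled male hold transcripts of a Y chromosome. Reads misassigned alike in every library would give the same ratios. Argued against is also an exchange of labels between the groups, as the lowest Y-linked count in a library labelled male was 5148. So is a minor share of male cells in the libraries labelled female alone. The lower 95% bound of their ratio to those labelled male was 0.975. A candidate explanation is that male mice were the source of the libraries labelled female, for which the ratio would be near 1 and was 1.03. Pooling of both sexes in the same share in every library, a minor male share included, cannot be told apart from it. The upper bound of 1.09 allows either, and Xist, which would separate them, is not analysed here.

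Type I interferon response genes were lower in the libraries labelled female. A smaller share of B cells and dendritic cells cannot be told apart from a change within neutrophils, since the median log2 change of the list (-0.65) lay between that of dendritic cell genes (-0.59) and that of Ccr7 (-1.04), their called marker that fell most. Against it as the whole cause, 9 of 53 interferon genes fell further than Ccr7 by over 2 SE of the difference, but these are the most changed of the list. A shift of the whole scale is argued against, since the list's median lay at -0.65 relative to that of all other genes, a difference that a common factor leaves as it is. A difference in handling during cell isolation cannot be told apart from the groups, since immediate early genes fell with them (median log2 -0.38) and no handling record was used here. This limit holds for the other differences between the groups too. For the sex in the labels, the ratio of Y-linked sums was 1.03 (95% interval 0.975 to 1.09). So far as these transcripts came from a Y chromosome, this argues against a large difference in the share of male cells as the cause. Any other difference between the animals was not tested.

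Mature neutrophil genes were higher in the libraries labelled female. Fewer cells of other types alone would raise all neutrophil genes alike. Primary granule genes had a median log2 change of -0.0061 and an upper quartile of 0.0991, against a lower quartile of 0.275 in mature neutrophil genes. This argues against it as the whole cause. A part in the rise is not excluded, since B cell and dendritic cell genes fell. The median primary granule gene, Nkg7, is also listed for T and NK cells. A smaller share of immature dividing neutrophils would lower cell cycle genes, by an amount that depends on the unknown starting share. That list had members on both sides and did not fall (median 0.0040, from -0.0062 to 0.012 without 1 library; adjusted p = 0.944 by camera). So far as its transcripts came from neutrophils, this argues against a large drop in that share. A small drop cannot be told apart from a change within mature cells.

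Another 2 hypotheses were tested. Lower Ciart, a clock gene, could point to a different time of day of collection, for which at least 4 of 8 other clock genes of the same phase were to pass in its direction and fewer than 2 were to count against. Of the 8, only 1 passed (Tef, log2 -0.40, adjusted p = 0.02415), which met the bound set beforehand for counting against. That bound was unsound, since a gene that misses the threshold does not show the absence of a change. The fitted change had the direction of Ciart in 8 of 8, but some lay within 1 SE of 0, such as Per2 (log2 -0.086, SE 0.092) and Nr1d1 (-0.21, SE 0.36). Outside the 8, Arntl was also lower (-0.11, SE 0.16) and Clock higher (0.19, SE 0.097), neither past the threshold. A different time of day stays open. The call of Ciart itself (log2 -0.74, adjusted p = 0.00841) was lost without male replicate 3 (adjusted p = 0.0517), and that of Tef without male replicate 1 (0.107), male replicate 3 (0.0908) or female replicate 2 (0.133). Lower mitochondrially encoded transcripts were not matched by a shift of nuclear-encoded respiratory chain genes, whose median log2 change was 0.0064, though that list fell by 0.065 without female replicate 3.

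The 6 libraries can be divided into 3 and 3 in 10 ways, so no share under 0.05 can be reached. For 1656 genes past the threshold and for 1597 autosomal genes, 1 of 10 splits, the real one, gave as many, and the highest other split gave 0. Every other split places both labels in each group, which widens the spread within groups. The 0 is therefore no evidence on what caused the difference between the labels. For gene lists with the preset correlation the real split gave 16, again 1 of 10, and the highest other split gave 15.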
